A study of Rattus norvegicus with 12 samples.

How the data were processed

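Total RNA of 12 rat retinas, 6 Control and 6 IR, was hybridised to Illumina expression arrays, 1 array per sample. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase I, checked on a Bioanalyser, and turned into biotin-labelled cRNA with the Ambion TotalPrep kit. The authors' values came from BeadStudio version 2.0, per the submitters' processing notes, and its settings are not given in the sources used here. The deposited value table holds probe intensity on a linear scale for 22226 probes. By its values the deposited intensity was scaled between arrays (column means of 346 to 347) but not brought to 1 distribution (medians of 52.1 to 69.8), and no background was subtracted, since the mode of the intensities lay at 38.5 to 52.0 on the arrays. Scale is linear and direction is that of intensity; how the authors brought the means together is not given in the sources used here.

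A table of signals with detection p-values was also deposited by the authors, but its 24 columns are named by a chip number and a position that match no sample label, so it was not used. Those headers name 1 chip, and columns were joined to samples by name alone, not by order or values. The background correction from detection p-values (neqc) fixed in the design before the data were examined was therefore not run, and the fallback fixed with it was used. Intensity was transformed as log2(intensity + 16) and quantile normalized over the 12 arrays, because the columns shared a mean and not a distribution. Differences and folds are on this scale, which understates the change of dim probes. In place of detection p-values, chosen after the data were examined, each array's background was taken as the mode of its intensities with the spread of the values below the mode, and a probe counted as above background where it exceeded the upper 0.05 tail of that distribution, at an intensity of 44.4 to 59.9. Probes above background on at least 6 of the 12 arrays were tested, 14214 in all, and 8012 were not. Where a probe was above background on no array of a group, only a bound is given, against the higher of the dim probe's own value and the lowest signal above background on each array.

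Gene names came from the platform annotation supplied for the arrays, updated through gene identifiers in RefSeq's table for assembly GRCr8. A single symbol was found for 13192 probes, several for 0, and 9034 are unnamed here. Of the named probes 13151 were found in the RefSeq table and 41 kept the platform's name. The build behind the array is not named, so no coordinates are given. The tested probes included 9510 named ones for 9427 genes.

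IR was compared with Control in limma version 3.58.1 (statmod 1.5.0, R 4.3.3) with lmFit and eBayes, two-sided, without covariates, and Benjamini-Hochberg adjustment over the tested probes. Calls are at an adjusted p under 0.05. Standard errors are those of the moderated fit. Before the data were examined, 39 gene lists were fixed from textbook knowledge, 11 main ones and 28 others, none chosen on these samples. Lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01, on the probe with the highest mean per gene, adjusted over 37 lists. Camera compares a list's genes with all other genes. Genes named are the 12 with the largest increase and the 12 with the largest decrease among called probes with separated groups and a symbol that is not a predicted model, up to 4 called members of each list with the smallest adjusted p, and a set of genes fixed in advance, of which some are not reported here. For a gene with several probes the first rule takes the most changed probe and the others the brightest. A list score is the mean over its genes of the log2 value minus the Control mean. Spread and relations between list scores were tested with exact permutation over 924 splits or 720 pairings. No 2 arrays held the same values, the smallest root mean square difference between 2 arrays being 0.238 on the log2 scale.

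The fit and the list test were tried in 5 simulations of normal values on the normalized log2 scale. Each had 200 changed probes among 14214 for the comparison of IR with Control. Means were those of the Control arrays, and spreads were the moderated ones of the real fit. The background estimate, filter, offset and normalization were not run on simulated values, so the rates below do not cover them. The fit recovered 70.0% of probes changed by 0.5 and 95.0% of probes changed by 1 on the log2 scale, with 4.5% false calls. Of 185 unshifted lists 0 were called, and a list of 20 genes shifted by 0.3 was called in 5 of 5 simulations. Simulated genes varied independently of each other. In the real data the estimated correlation within a list ran from -0.03 (astrocytes) to 0.94 (crystallins). The simulations therefore do not show how often the preset correlation calls unshifted lists of correlated genes. Alternatives covered the replicate number as a block, an offset of 50, median scaling, cyclic loess, the values as deposited, the filter on dim probes, array weights, a trended and robust eBayes, each array left out in turn, and for lists an estimated correlation, fry and the mean of a gene's probes. Normexp background correction of the deposited values, with offsets of 16 and 50, and the removal of IR 3 and Control 5 together were added after the data were seen.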

Results

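Gene expression was measured on Illumina bead arrays in retinas of Sprague-Dawley rats, an outbred albino laboratory strain. Of the 12 arrays, 6 held RNA of control retinas (Control 1 to 6) and 6 held RNA of retinas labelled as having undergone transient ischemia followed by reperfusion (IR 1 to 6), in which the blood supply is interrupted and then restored. The series description names ischemic preconditioning as the arrayed treatment, whereas every sample label gives ischemia followed by reperfusion, and the sample labels are followed here. The labels used here give neither the duration of the ischemia nor the time of reperfusion. Nothing in the labels says that the 6 retinas of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. The table held 22226 probes, of which 14214 were above background on at least 6 of the 12 arrays and were tested. Between 13630 and 14735 probes were above background on an array, and the median intensity was between 52.1 and 69.8. Arrays correlated with each other at r = 0.949 to 0.990 across probes, which are not independent replicates. The number of arrays limits the precision of every value below.

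The series description asks how injury of the retina relates to apoptosis, vascular permeability and the VEGF and TNF pathways. The arrays bear on this only through transcripts, of which some were not measured, and they do not measure permeability. Injured retinas carried higher transcript levels of microglial, reactive glial, complement, antigen presentation and matrix genes, and lower levels of retinal ganglion cell genes and of several cone genes. The gene with the largest called increase was Lgals3, which encodes the phagocyte lectin galectin-3. It was at a log2 intensity of 11.25 ± 0.60 (SD, n = 6) in IR and 7.90 ± 0.48 (SD, n = 6) in Control retinas, a difference of 3.34 ± 0.28 (SE) or 10.2-fold (limma adjusted p = 1.2e-04). Hmox1, the inducible heme oxygenase, was 6.34-fold higher (log2 difference 2.67 ± 0.36, SE). The largest called decrease was in Egfl6, an EGF-repeat matrix protein, at -1.36 ± 0.13 (SE) on the log2 scale (adjusted p = 2.3e-04). In limma's test with Benjamini-Hochberg adjustment, 436 probes were higher and 382 lower in IR, together 818 or 5.75% of the probes tested. They covered 360 named genes that rose and 287 that fell. Changes of at least 2-fold were mostly increases, with 97 probes higher and 6 lower. All 6 IR values lay on 1 side of all 6 Control values for 552 of the tested probes (3.88%, against 0.216% by chance), 478 of them called. The balance of directions depended on the scaling. Increases made up 53.3% of the calls after quantile normalization, 30.9% after median scaling, 64.7% after cyclic loess and 77.2% in the values as deposited, where the median of all tested probes lay at 0.13 on the log2 scale in place of -0.02. The number of probes lower fell from 382 to 243 without Control 4, to 239 without IR 3, to 248 without IR 5 and to 203 without IR 6. The 6 probes lower by at least 2-fold became 11 without Control 1 or IR 4, 10 without IR 1 and 3 without IR 6.

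The other genes among the 12 largest separated increases belonged to several functions. Cp, the copper-carrying ferroxidase ceruloplasmin, was higher by 2.26 ± 0.21 (SE) on the log2 scale, and Timp1, a tissue inhibitor of metalloproteinases, by 2.09 ± 0.28 (SE). Spp1, the secreted phosphoprotein osteopontin, differed by 2.25, the tyrosine kinase gene Jak3 by 2.10, the lipid droplet coat gene Plin2 by 2.05, and both S100a4 and Tspo, a mitochondrial protein of activated glia, by 1.95. Tagln2 differed by 1.92, Pdpn, the membrane glycoprotein podoplanin, by 1.85, and the mitotic cyclin gene Ccnb2 by 1.84. All 12 were called, with adjusted p between 1.2e-04 and 0.0079. The 12 largest separated decreases were smaller, from -1.36 to -0.84. After Egfl6 came Fcer1a at -1.13 ± 0.14 (SE), the alpha chain of the IgE receptor, then Sntg2 and the neuropeptide gene Cartpt at -0.98 each, the phosphatase gene Ppef1 at -0.96, and the middle-wavelength cone opsin Opn1mw at -0.95. Nphs1 and Reep6 were each at -0.93. A second probe of Reep6 was at -0.01 (adjusted p = 0.99), so its probes disagreed. The last 4 of this set were the neuronal transcription factor gene Myt1l at -0.86, the connexin gene Gjb6 at -0.85, and Stkld1 and the cone phosphodiesterase gene Pde6c at -0.84 each. With normexp and an offset of 16, Opn1mw was at -1.56 and Gjb6 at -1.31.

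**Figure D1:**
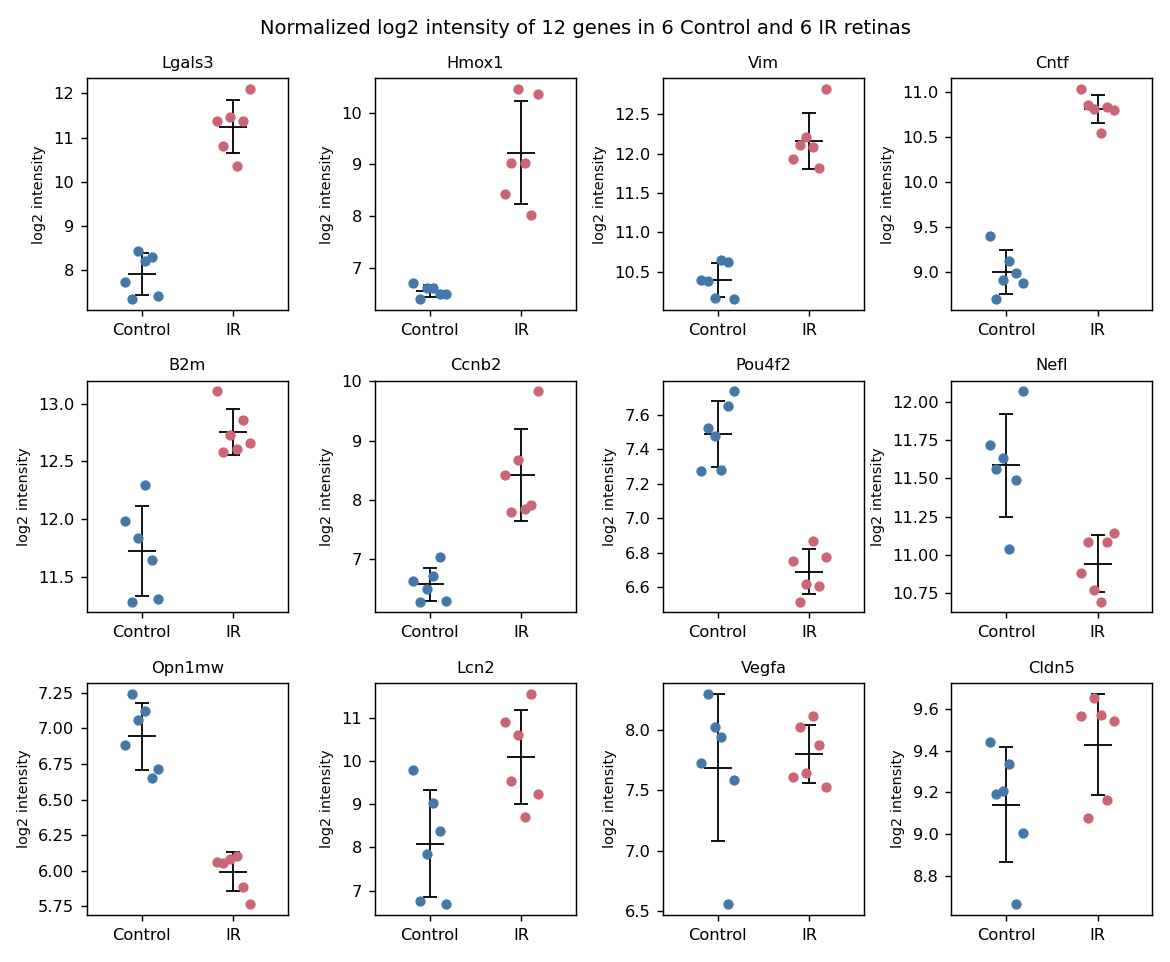
Normalized log2 intensity of 12 genes (vertical axes) in the 6 Control and 6 IR retinas; each point is an array, the horizontal mark is the group mean and the bar its SD. Lgals3 lies at 11.25 ± 0.60 in IR and 7.90 ± 0.48 in Control, Pou4f2 is lower in all 6 IR arrays than in all 6 Control arrays, and Lcn2, Vegfa and Cldn5 overlap between the groups.

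Genes of microglia and macrophages, the resident and infiltrating phagocytes, rose as a group. Of 30 measured genes, 21 were higher and none lower (28 higher when adjusted over the list alone). The median log2 difference was 0.65 (camera adjusted p = 2.8e-24, and 0.046 with an estimated correlation of 0.45). Besides Lgals3, the genes with the smallest adjusted p were the endotoxin co-receptor gene Cd14 at 1.07 ± 0.11 (SE), Ncf1, a subunit of the phagocyte oxidase, at 1.03 ± 0.15 (SE), and the leukocyte tetraspanin gene Cd53 at 0.49 ± 0.07 (SE). All 6 IR values of each lay above all 6 Control values. Cd53 was above background on 1 Control array, so its difference is one from near background, and normexp with an offset of 16 gave 0.91. Complement genes followed, with a median of 0.78 (camera adjusted p = 3.5e-09, and 0.046 with an estimated correlation). Of 14 measured, 7 were higher (12 adjusted over the list alone). Among them were Clu, the complement inhibitor clusterin, at 1.37, the classical pathway proteases C1s at 1.21 and C1r at 1.07, and C2 at 0.97. The call of C2 was lost without Control 2, IR 3 or IR 6 (log2 difference 0.79 to 1.08 over all settings). The neutrophil list did not pass the test (0 of 6 called, none adjusted over the list alone, median -0.02, adjusted p = 0.61). Of the lymphocyte genes only 3 were measured, too few for the list test, and none was called over all probes or adjusted over the list alone. Red blood cell genes did not pass the test either (0 of 7 called, none adjusted over the list alone, median 0.01, adjusted p = 0.61).

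Genes of reactive gliosis, the injury response of Müller glia and astrocytes, rose as well. Of 21 measured genes 12 were higher and none lower (19 adjusted over the list alone). The median was 0.90 (camera adjusted p = 4.3e-17, and 0.026 with an estimated correlation). Vim, the intermediate filament vimentin, was 3.42-fold higher (1.77 ± 0.15, SE, adjusted p = 1.2e-04), Cp and Timp1 are given above, and the sphingosine kinase gene Sphk1 was at 1.18 ± 0.16 (SE). Edn2, the vasoconstrictor endothelin-2, rose by 1.11 ± 0.22 (SE, adjusted p = 0.011). Lcn2, the acute phase protein lipocalin-2, had a difference of 2.00 ± 0.60 (SE) that did not pass the threshold (adjusted p = 0.071), with SDs of 1.09 in IR and 1.24 in Control retinas. It passed in 5 other settings, among them the fits without Control 1 and without IR 4 (adjusted p 0.033 to 0.15 over all settings). The acute phase and STAT3 list had a median of 0.67 (camera adjusted p = 2.5e-11, and 0.022 with an estimated correlation). This list had 10 of 21 genes higher and none lower (13 higher and 1 lower adjusted over the list alone). Its leading gene was Cntf, the ciliary neurotrophic factor, which was 3.51-fold higher (1.81 ± 0.11, SE, adjusted p = 8.5e-06). Myc rose by 0.67 ± 0.09 (SE) and A2m, the protease inhibitor alpha-2-macroglobulin, by 1.55 ± 0.24 (SE). Stat3 itself was at 0.57 ± 0.18 (SE, adjusted p = 0.081) and passed in 4 other settings, among them the fits without Control 5 and without IR 4 (adjusted p 0.0099 to 0.15 over all settings). The list of resting Müller glia functions also moved up, with 2 of 22 genes called (6 higher and 2 lower adjusted over the list alone), a median of 0.13 and an adjusted p of 0.010, which with an estimated correlation was an adjusted p of 0.24. The call was also lost in the values as deposited (median 0.25, adjusted p = 0.21) and with array weights (adjusted p = 0.067), and without IR 3 the median was 0.086. Its 2 called genes were Pdpn and Clu, which are not limited to resting glia. Of 8 astrocyte genes, Id3 was lower at -0.38 (2 lower adjusted over the list alone), a call lost in 7 of the 12 fits that left out 1 array (adjusted p up to 0.081 over all settings), and the list did not pass the test (median -0.11, adjusted p = 0.32), although it passed with fry, downward (adjusted p = 0.028).

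**Figure D2:**
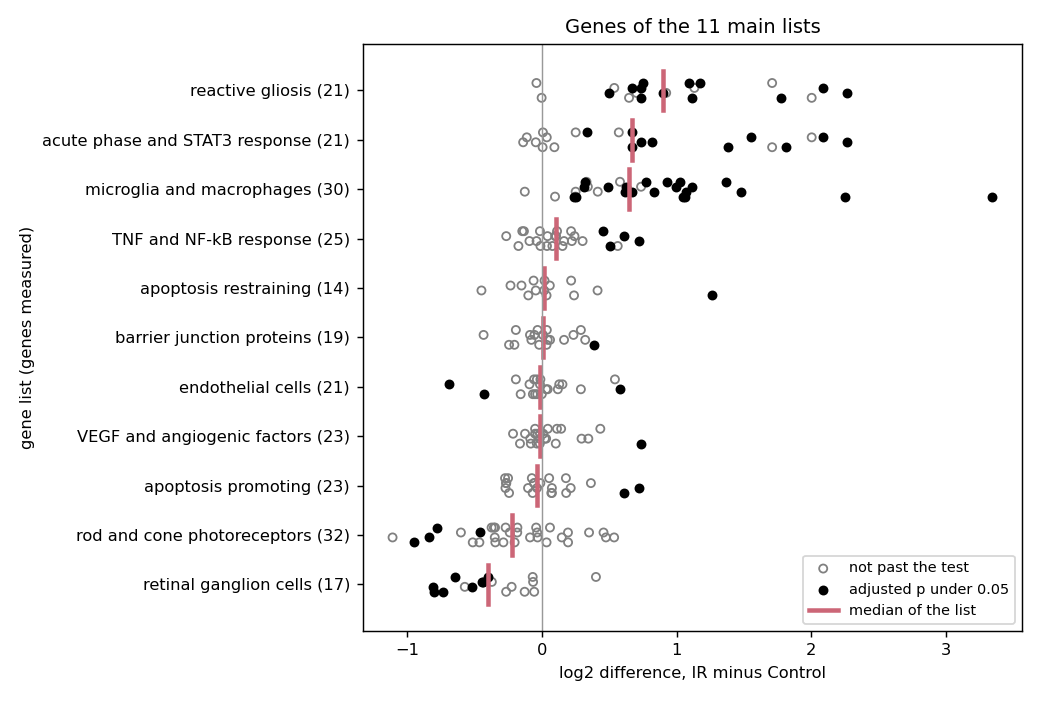
Log2 difference between IR and Control (horizontal axis) of each measured gene in the 11 main lists (vertical axis, genes measured in parentheses); filled points are genes past an adjusted p of 0.05 over all probes, open points are not, and the red mark is the list's median. Medians run from -0.40 for retinal ganglion cells to 0.90 for reactive gliosis, and the apoptosis, VEGF, endothelial and barrier lists have medians near 0.

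Retinal ganglion cell genes, which mark the output neurons of the retina, fell. Of 17 measured genes 8 were lower and none higher (11 lower adjusted over the list alone). The median was -0.40 (camera adjusted p = 8.7e-07, and 0.026 with an estimated correlation). The transcription factor gene Pou4f2 was at -0.80 ± 0.09 (SE, adjusted p = 5.0e-04), 1.74-fold lower, the calcium sensor gene Vsnl1 at -0.81 ± 0.13 (SE), and the neurofilament genes Nefm at -0.44 ± 0.09 (SE) and Nefl at -0.64 ± 0.15 (SE). The call of Nefl was lost without IR 3, at an adjusted p of up to 0.061 over all settings. Thy1, a surface glycoprotein of these cells, had a difference of -0.06 ± 0.35 (SE, adjusted p = 0.96), and Sncg one of -0.57 ± 0.19 (SE, adjusted p = 0.11), which passed in 3 other settings (adjusted p 0.032 to 0.20 over all settings). Of 32 photoreceptor genes 4 were lower and none higher (8 lower adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0033). With an estimated correlation the adjusted p was 0.32, and with fry, which tests the list against 0, it was 0.093. The 4 genes were Opn1mw, Pde6c, the cone transducin gene Gnat2 at -0.78 ± 0.16 (SE) and Guca1a, a guanylate cyclase activator, at -0.46 ± 0.08 (SE). Opn1mw, Pde6c and Gnat2 belong to cones, and of 10 rod genes, grouped after their values were seen, none was called and 5 lay below 0 and 5 above, from Cnga1 at -0.36 to Gnat1 at 0.19. The score of the photoreceptor list was -0.49 in Control 5, against 0.04 to 0.22 in the other Control arrays, and without Control 5 the list median was -0.35 (adjusted p = 4.3e-06). After median scaling it was -0.42 and after cyclic loess -0.15. The call of Guca1a was lost with cyclic loess, and that of Gnat2 without IR 3 and Control 5 together (adjusted p = 0.054).

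Further lists covered inner retinal neurons and synapses. Amacrine and horizontal cell genes had 3 of 22 lower and 1 higher (4 lower and 1 higher adjusted over the list alone), with a median of -0.20 and an adjusted p of 0.0064, which with an estimated correlation was an adjusted p of 0.14. Calbindin (Calb1) was at -0.47, tyrosine hydroxylase (Th), the dopamine-synthesizing enzyme, at -0.44, and the transcription factor gene Tfap2a at -0.74, whereas the tachykinin gene Tac1 was at 0.43. Tac1, Th and Tfap2a lost their calls in 8, 5 and 9 of the 12 fits that left out 1 array, with adjusted p up to 0.27, 0.13 and 0.12 over all settings, and Calb1 lost its call without IR 3 and Control 5 together (adjusted p = 0.055). Bipolar cell genes did not pass the test (1 of 14 lower, also 1 adjusted over the list alone, median -0.18, adjusted p = 0.14), although the calcium-binding secretagogin gene Scgn was at -0.70 ± 0.12 (SE, adjusted p = 0.0048). The list passed in the values as deposited (median -0.09, adjusted p = 0.027) and with fry (adjusted p = 0.039). Synapse genes had 2 of 28 lower (4 adjusted over the list alone), with a median of -0.11 and an adjusted p of 0.028, which with an estimated correlation was an adjusted p of 0.32. The glutamate receptor gene Grin1 was at -0.60 and the vesicular glutamate transporter gene Slc17a6, which also marks ganglion cells, at -0.52, a call lost in 6 of the 12 fits that left out 1 array (adjusted p up to 0.081 over all settings). Grin1 lost its call without IR 3 and Control 5 together (adjusted p = 0.057). The synapse list lost its call after median scaling (adjusted p = 0.067), with probes above background at 0.01 on all 12 arrays (adjusted p = 0.089), and without Control 1 (0.061), Control 2 (0.079) or IR 1 (0.058), each an adjusted p. Its median was -0.066 without IR 6 and turned to 0.061 in the values as deposited, where camera still gave a downward direction.

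The questions of the series on apoptosis, VEGF and the vascular barrier concern lists that did not pass the test. Of 23 genes promoting apoptosis 2 were higher and none lower (3 adjusted over the list alone), Bak1, a pore-forming BCL-2 family member, at 0.61 ± 0.11 (SE) and the TNF receptor gene Tnfrsf1a at 0.72 ± 0.15 (SE). The median was -0.04 while the camera direction and the mean of 0.02 were upward (adjusted p = 0.61). Of 14 genes restraining apoptosis, Bcl2a1, a BCL-2 relative of leukocytes, rose by 1.26 ± 0.23 (SE), the only call in either adjustment, with 1 adjusted over the list alone (list median 0.02, adjusted p = 0.61). Bcl2l1 was at -0.06 ± 0.05 (SE). Of 23 VEGF and angiogenic genes, Fgf2 alone was called, at 0.74 ± 0.15 (SE), with 2 adjusted over the list alone (median -0.01, mean 0.06 and camera direction upward, adjusted p = 0.44). In the values as deposited the median of this list was 0.18 (adjusted p = 0.028). Vegfa was at 0.11 ± 0.24 (SE, adjusted p = 0.86), with a direction that turned under some settings (-0.11 to 0.23), Flt1 at -0.01 ± 0.05 (SE) and Angpt2 at -0.09 ± 0.11 (SE). Of 21 endothelial genes 1 was higher and 2 lower, the same numbers as when adjusted over the list alone (median -0.01, mean 0.002, with camera upward and fry downward, adjusted p = 0.88). Von Willebrand factor (Vwf) was at 0.58, the transporter gene Slco1c1 at -0.43 and the fenestral diaphragm gene Plvap at -0.69. Vwf and Plvap lost their calls in 7 and 9 of the 12 fits that left out 1 array, with adjusted p up to 0.085 and 0.086 over all settings. Slco1c1 lost its call with the replicate block and without IR 3 and Control 5 together (adjusted p up to 0.074 over all settings). Of 19 barrier junction genes, Jam3, a junctional adhesion molecule, was higher at 0.38 ± 0.07 (SE), the only call in either adjustment, with 1 adjusted over the list alone (list median 0.01, adjusted p = 0.41), and its call was lost after median scaling (adjusted p = 0.051). The tight junction genes Cldn5, Ocln and Tjp1 had differences of 0.29 ± 0.14, 0.03 ± 0.05 and -0.03 ± 0.10 (SE, adjusted p = 0.28, 0.80 and 0.91). Pericyte and smooth muscle genes had 1 of 9 called (2 adjusted over the list alone), desmin (Des) at 0.28, a call lost in 9 of the 12 fits that left out 1 array, with a list median of 0.08 and an adjusted p of 0.055. That list passed after median scaling (median 0.08, adjusted p = 0.0075), in the values as deposited (median 0.26, adjusted p = 0.0042), without a filter (median 0.03, adjusted p = 0.046), with array weights (adjusted p = 0.046), and without Control 3, Control 5, IR 4, IR 5 or IR 6.

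The list of TNF and NF-kB response genes passed the test upward. Of 25 genes 4 were higher and none lower (5 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0018), which was 0.30 in the values as deposited. With an estimated correlation the adjusted p was 0.19. The called genes were Ptgs2, the inducible cyclooxygenase, at 0.50 ± 0.10 (SE), Tnfrsf1a, the interferon-regulated transcription factor gene Irf1 at 0.61 ± 0.15 (SE) and the chemokine gene Cxcl1 at 0.45 ± 0.12 (SE). Cxcl1 lost its call in 11 of the 12 fits that left out 1 array, and Irf1 in 5 of them (without Control 4 and without IR 2, 3, 5 or 6) and after median scaling, with adjusted p up to 0.084 and 0.098 over all settings. With normexp and an offset of 16 Cxcl1 was at 0.73. The chemokine gene Ccl2 was at 0.56 ± 0.16 (SE, adjusted p = 0.053), with all 6 IR values above all 6 Control values, and it passed in 9 other settings, among them the fits without IR 2 and without IR 4 (adjusted p 0.0029 to 0.11 over all settings). The adhesion molecule gene Icam1 was at 0.22 ± 0.12 (SE, adjusted p = 0.33) and passed in the values as deposited (adjusted p = 0.0093). The probe of Tnf was above background on 1 IR and 0 Control arrays, and those of Bax and Cdh5 on none, so these genes were not tested. Kdr, Gfap, Pou4f1 and Glul, fixed in advance as genes to report, had no probe with that symbol in the annotation used here.

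The antigen presentation and interferon lists passed the test upward. The MHC class I and antigen processing list had a median of 0.43 (camera adjusted p = 8.0e-09, and 0.014 with an estimated correlation). Of its 17 genes 6 were higher (8 adjusted over the list alone). They included B2m, the class I light chain, at 1.04 ± 0.16 (SE), the immunoproteasome gene Psmb8 at 1.35 ± 0.21 (SE) and RT1-T24-4 at 1.17 ± 0.15 (SE). RT1-A2 was at 1.52 ± 0.35 (SE), a call lost without IR 3 (adjusted p up to 0.054 over all settings). In the MHC class II list 2 of 4 genes were higher (3 adjusted over the list alone), the peptide-loading genes RT1-DMb at 1.69 ± 0.21 (SE) and RT1-DMa at 1.28 ± 0.16 (SE). Its adjusted p was 0.0013, and with an estimated correlation the adjusted p was 0.089. Of 22 interferon-stimulated genes 6 were higher (10 adjusted over the list alone). Among them were Gbp2 at 0.93 ± 0.10 (SE), Ifitm1 at 0.64 and Cxcl11 at 0.49. The list's median was 0.43 (camera adjusted p = 3.9e-08, and 0.046 with an estimated correlation). Cxcl11 was above background on 1 Control array, and normexp with an offset of 16 gave 0.90 for it and 1.04 for Ifitm1. The inflammasome and necroptosis list had 2 of 10 genes higher (2 adjusted over the list alone) and an adjusted p of 2.0e-04, which with an estimated correlation was an adjusted p of 0.076. Its called genes were Casp1, the inflammasome protease, at 0.91 ± 0.12 (SE) and the adaptor gene Pycard at 0.95 ± 0.24 (SE). The call of Pycard was lost without Control 2, 3 or 6 and without IR 1, 3 or 5 (adjusted p up to 0.084 over all settings).

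The matrix and cell cycle lists passed the test upward. Of 29 extracellular matrix genes 10 were higher (12 adjusted over the list alone). Among them were Fn1, fibronectin, at 1.29 ± 0.19 (SE) and the plasminogen activator gene Plat at 0.57 ± 0.09 (SE). The list's median was 0.24 (camera adjusted p = 1.3e-09, and 0.046 with an estimated correlation). That median was 0.40 in the values as deposited and 0.39 after normexp with an offset of 16. Of 31 cell cycle genes 10 were higher (17 higher and 1 lower adjusted over the list alone), with a median of 0.32 and an adjusted p of 3.7e-10, which with an estimated correlation was an adjusted p of 0.16. Beside Ccnb2, Rrm2, a ribonucleotide reductase subunit, was at 1.38 ± 0.17 (SE), the mitotic kinase gene Aurkb at 0.82 ± 0.16 (SE) and Ube2c at 0.65 ± 0.13 (SE). Aurkb and Ube2c were above background on 3 and 2 Control arrays, and normexp with an offset of 16 gave 1.34 and 1.08. The median of the cell cycle list was 0.48 without Control 3, 0.61 in the values as deposited and 0.55 after normexp with an offset of 16. Its mean score was 1.03 in IR 6 and 0.24 to 0.52 in the other IR arrays. IR 6 also had the lowest amacrine and horizontal cell score, at -0.44.

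**Figure D3:**
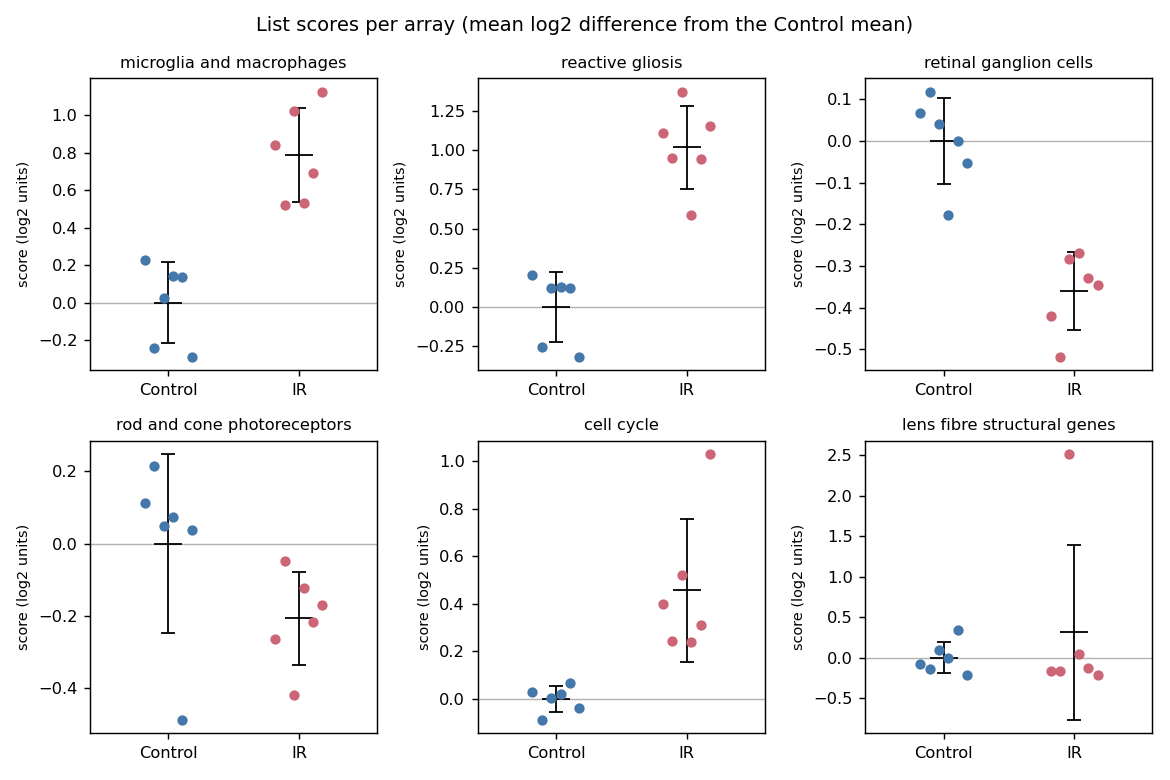
Score of 6 gene lists (vertical axes, mean log2 difference of the list's genes from their Control mean) in each of the 6 Control and 6 IR arrays; points are arrays, the mark is the group mean and the bar its SD. All 6 IR arrays lie above all 6 Control arrays for microglia, gliosis and cell cycle genes and below them for retinal ganglion cell genes, and IR 3 alone has a high lens fibre score, at 2.51.

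Further lists covered stress responses, metabolism and growth factors. Of 25 oxidative stress and metal response genes 3 were higher (4 adjusted over the list alone), Hmox1, the glutathione peroxidase gene Gpx1 at 1.02 ± 0.14 (SE) and the cystine transporter gene Slc7a11 at 0.26 ± 0.07 (SE). The median was 0.14 and the adjusted p 0.0012, which with an estimated correlation was an adjusted p of 0.10, and in the values as deposited 0.12. After median scaling the median was 0.004. Slc7a11, above background on 1 Control array, lost its call in 9 of the 12 fits that left out 1 array, and normexp with an offset of 16 gave 0.51. The list of axon injury and immediate early genes had 7 of 25 genes higher and 1 lower (9 higher and 1 lower adjusted over the list alone), with a median of 0.13 and an adjusted p of 5.6e-05, which with an estimated correlation was an adjusted p of 0.22. Without Control 3 its median was 0.22. Fos, Egr1 and Klf6, transcription factor genes induced by stimulation, were at 0.80 ± 0.09, 0.85 ± 0.12 and 0.67 ± 0.12 (SE), and Ecel1, above background on 1 Control array, was at 0.54 ± 0.09 (SE), or at 0.998 with normexp and an offset of 16. Of 20 hypoxia and glycolysis genes 1 was lower and none higher (2 lower adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.025, which with an estimated correlation was an adjusted p of 0.30. The called gene was the glycolytic enzyme gene Pgk1 at -0.43 ± 0.09 (SE). The list's call was lost without Control 2 (adjusted p = 0.078) and without IR 6 (median -0.098, adjusted p = 0.071), and with probes above background at 0.01 on all 12 arrays (adjusted p = 0.060). The remaining stress lists did not pass the test. Heat shock and chaperone genes had 2 of 15 called, as when adjusted over the list alone, Hspa2 at 0.99 ± 0.13 (SE) and Hspb1 at 1.09 ± 0.28 (SE), with a median of 0.02 (adjusted p = 0.61). The call of Hspb1 was lost in 9 fits that left out 1 array. The p53 and DNA damage list had 1 of 13 called, also 1 adjusted over the list alone, Gadd45g at 1.01 ± 0.20 (SE), with a median of -0.03, a mean of 0.07 and an upward camera direction (adjusted p = 0.61). The endoplasmic reticulum and integrated stress list had Cebpb at 0.82 ± 0.16 (SE) and Trib3 at -0.86 ± 0.17 (SE) among 21 genes, the same 1 higher and 1 lower adjusted over the list alone, with a median of 0.02, a mean of -0.06, camera upward and fry downward, and an adjusted p of 0.86. Oxidative phosphorylation genes had 0 of 30 called, and none adjusted over the list alone (median -0.07, adjusted p = 0.30), although the list passed after median scaling (median -0.28, adjusted p = 0.0022) and in the values as deposited (median -0.13, adjusted p = 8.0e-05). Growth factor genes moved both ways, with 5 of 20 higher and 2 lower (5 higher and 4 lower adjusted over the list alone, median 0.04, adjusted p = 0.41), and the list passed with fry, upward (adjusted p = 0.0085). Mdk, the heparin-binding factor midkine, was 2.82-fold higher, with an SE of 0.23 on the log2 scale. The probe of Clcf1, a cytokine of the Cntf family, was not above background on any Control array, and its level in IR was at least 1.15-fold higher (adjusted p = 0.0033).

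Genes of neighbouring eye tissues were examined beside those of the retina. Lens transcripts stood out in 1 array, IR 3, with a crystallin score of 4.47 against -1.58 to 0.94 in the other 11 arrays and a lens fibre structural score of 2.51 against -0.22 to 0.34. Between the groups neither list passed the test (crystallins 0 of 7 called, median 0.22, adjusted p = 0.69; lens fibre genes 0 of 7 called, median 0.40, adjusted p = 0.41), and none of their genes was called when adjusted over the list alone. Without IR 3 the crystallin median was -0.68 (adjusted p = 0.043). Retinal pigment epithelium genes had 0 of 11 called, and none adjusted over the list alone (median -0.21, adjusted p = 0.16). That list passed without Control 1 (adjusted p = 0.048) and without IR 4 (adjusted p = 0.036), and with the replicate block (adjusted p = 0.033). Of the cornea, iris and ciliary body list 3 genes were measured, too few for the list test. Opcml was called at 0.49 ± 0.10 (SE), also the only call when adjusted over the list alone. Its call was lost after median scaling (limma adjusted p = 0.061). A call of 1 gene, above background on all 6 arrays of each group, is not by itself a sign of those tissues.

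In all, 19 of the 37 lists tested passed camera's test with its preset correlation of 0.01, 14 upward and 5 downward. With an estimated correlation 8 lists kept an adjusted p under 0.05, namely retinal ganglion cells (0.026), reactive gliosis (0.026), acute phase and STAT3 response (0.022), microglia and macrophages (0.046), complement (0.046), MHC class I and antigen processing (0.014), interferon-stimulated genes (0.046) and extracellular matrix (0.046).

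Injured retinas did not differ more among themselves than control retinas in a test of the distance to the group mean. The mean distance was 0.223 in IR and 0.238 in Control on the log2 scale, a difference of -0.01 (two-sided exact permutation test over 924 splits, p = 0.68). Control 5 was the array farthest from its group, at 0.350. Relations between list scores were tested within each group, over 6 arrays, as 10 relations in all, and none passed the adjustment. The largest r was between the TNF and apoptosis-promoting scores of Control retinas (Pearson r = 0.83, exact permutation p = 0.035, adjusted p = 0.35; Spearman rho = 0.94, exact permutation p = 0.017, adjusted p = 0.17), and without the 2 arrays farthest from the median TNF score r was 0.88. In IR retinas the same relation had r = 0.60 (exact permutation p = 0.20, adjusted p = 0.37; rho = 0.54, exact permutation p = 0.30, adjusted p = 0.50), and without 2 arrays r = -0.05. The relation of apoptosis-promoting to barrier junction scores, which bears on the title of the series, had r = -0.22 in IR (exact permutation p = 0.62, adjusted p = 0.69; rho = -0.14, exact permutation p = 0.80, adjusted p = 0.89; r = -0.27 without 2 arrays) and r = 0.59 in Control retinas (exact permutation p = 0.22, adjusted p = 0.37; rho = 0.60, exact permutation p = 0.24, adjusted p = 0.50; r = 0.96 without 2 arrays).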

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

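The tests of lens, cone and ganglion cell genes in this part were chosen after the results were seen, the bound of 2 SE in the crystallin test was set after its value was known, and the count of other splits was planned before. Values of the named genes, list scores and 3 measures per array were examined within each group of 6 arrays for an array whose gap to its nearest neighbour was large against the range of the group. Of 294 such groups 24 had one, where chance gives about 1 in 20, or 14.7. For list scores it was 12 of 74, against 3.7 by chance, and 4 of these were in Control 5 and 3 in IR 3. For genes it was 12 of 214, against 10.7.

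The comparison of IR with Control was set against other splits of the 12 arrays into 6 and 6, of which 100 of 462 were drawn, the real one included. Only the real split, 1 of 100, gave 818 or more called probes, and the highest of the others gave 27. Within the splits drawn, this argues against a random grouping of the arrays as the source of the number of calls. Other splits mix the groups, so a real difference adds to their spread and lowers their counts. The count does not bear on single calls or on a technical difference that lies along the groups. The split with 27 calls was the real one with Control 5 and IR 4 exchanged.

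The first pattern is the lens signal of IR 3, which lay far above the other IR arrays in the scores for crystallins (4.47, others of the group -1.58 to 0.35) and for lens fibre structural genes (2.51, others -0.22 to 0.04). Of 14 lens genes measured, 13 were higher in IR 3 than in all other arrays, those with the brightest probes there being Crygc at 13.65, Cryba1 at 13.64 and Cryba2 at 13.49 on the log2 scale, where probe signals do not rank transcripts by amount and the other arrays reached at most 10.79, 10.14 and 9.56. Lens tissue or lens RNA in that sample is a candidate explanation that stays open, since the lens fibre score of 2.51, outside the range of the other 11 arrays (-0.22 to 0.34), is the observation that raised it and no independent test of it. A rise of crystallins with the injury is the biological alternative, and the other 5 IR arrays had a crystallin score 0.84 below Control (difference -0.84, exact permutation p = 0.13), which lies on the other side of that prediction without excluding it. The retina also expresses some crystallins, Cryab among them.

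The second pattern is that cone genes were lower, while rod genes as a set showed no clear difference. The cone score differed by -0.77 ± 0.11 (SE, 5 genes) and the rod score by -0.03 ± 0.14 (SE, 10 genes, all of both sets also in the photoreceptor list), and the sign of the rod score turned with the scaling (-0.15 after median scaling, 0.11 after cyclic loess and 0.01 in the values as deposited). Over the fits that left out 1 array the rod difference ran from -0.14, without Control 5, to 0.03. A smaller fall of rod genes is therefore not excluded. The rod set was picked after the values were seen. Other genes of the photoreceptor list, Guca1a among them, are in neither set, and the mean difference over all 32 genes was -0.21. Rod probes of Sag, Prph2 and Rom1, at mean log2 intensities of 14.07 to 14.15, could show little of a fall. Part of a gap between cones and all 10 rod genes may come from these probes. A loss of photoreceptors as a whole, or dilution by RNA of other cells, requires both to fall alike, but the cone minus rod score differed between IR and Control by -0.75 (exact permutation p = 0.0022, the smallest that 924 splits can give) and by -0.61 without Control 5 (p = 0.0065, exact permutation), the array with a low rod score. A saturated signal of bright rod probes requires dimmer rod genes to fall like cone genes, and over the 4 rod genes no brighter than the brightest cone gene the difference was -0.78 (exact permutation p = 0.0065), and -0.48 (exact permutation p = 0.043) without Control 5 and without Slc24a1, which lay near background and could show little of a fall. A lower level of cone transcripts, from cone loss or from lower expression per cone, stays open as a hypothesis, rests on 5 genes of which 3 were called (Gnat2 not without IR 3 and Control 5 together), and was seen and tested on the same data.

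The third pattern is the decrease of ganglion cell genes. Dilution of neuronal RNA by that of reactive glia and immune cells requires genes of other retinal neurons to fall as far. Over 45 genes of rods, bipolar, amacrine and horizontal cells, without cones, the score differed by -0.14 ± 0.04 (SE), over 16 ganglion cell genes by -0.36 ± 0.06 (SE), and the difference of -0.22 had an exact permutation p of 0.0087. The cone score fell further than that of ganglion cells (-0.77), and with cone genes among the other neurons, 50 genes in all, the difference was -0.16 (exact permutation p = 0.041). The 10 rod genes are among the 45, and bright rod probes such as that of Sag, at a mean log2 intensity of 14.07, could show little of a fall. No version without rod genes was tested. The bipolar list and the amacrine and horizontal cell list had mean differences of -0.13 and -0.21. Within these limits, dilution alone is argued against by the smaller decrease outside cones but may account for part. What remains stays open between fewer ganglion cells and less transcript per cell, which these arrays cannot separate.

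The other values that stood apart in their group are given without explanation. In Control 5 the scores were -0.49 for photoreceptors (others 0.04 to 0.22), -0.26 for synapse genes, -0.17 for apoptosis restraining genes and -0.10 for p53 targets. In IR 3 the heat shock score was 0.33. That list shares Cryab with the crystallins, at a log2 intensity of 13.08 in IR 3 and 9.15 to 10.24 in the other arrays. The heat shock flag is therefore not fully separate from the lens signal. In IR 4 the scores were 0.031 for retinal pigment epithelium (others -0.35 to -0.24) and -0.019 for p53 targets. In IR 6 the cell cycle score was 1.03 (others 0.24 to 0.52) and the amacrine and horizontal cell score -0.44 (others -0.21 to -0.13), and in IR 1 the barrier junction score was 0.13. Among genes, on the log2 intensity scale, Control 5 was highest for Plin2 at 8.90 and Nefm at 8.60. Control 6 was lowest for Pdpn at 9.60, Irf1 at 8.45 and Reep6 at 11.96. Control 4 was highest for Gbp2 at 6.60 and Cd53 at 6.10, and Control 1 for Rrm2 at 6.67. IR 3 was highest for Hspb1 at 8.94 and Ptgs2 at 8.64, and IR 6 was highest for Aurkb at 7.61 and lowest for Nphs1 at 6.87.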

How the results depend on the processing

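The normexp settings and the removal of IR 3 and Control 5 together were chosen after seeing the data, and all others were planned. Of the main lists, ganglion cells (median -0.51 to -0.35 over the settings), gliosis (0.71 to 1.20), acute phase (0.29 to 0.82) and microglia (0.51 to 1.03) kept their direction and their call in every setting run. The 5 main lists that were not called had medians on both sides of 0, from -0.07 to 0.18 over all settings. With an estimated correlation the TNF and NF-kB list (median 0.10, adjusted p = 0.19, 1.4e-04 to 0.19 over all settings) and the photoreceptor list (median -0.22, adjusted p = 0.32, 4.3e-06 to 0.32 over all settings) no longer passed, nor did photoreceptors with fry (median -0.22, adjusted p = 0.093), and in the values as deposited the VEGF list passed (median 0.18, adjusted p = 0.028, up to 0.57 over all settings). Among the other lists, crystallins turned to a lower median without IR 3 (-0.68, camera adjusted p = 0.043, up to 0.93 over all settings). Their median ran from -0.68 to 0.43 over the fits that left out 1 array, and IR 3 carried the lens transcripts. That call used the preset correlation of 0.01, against an estimate of 0.94, and over arrays the exact permutation p without IR 3 was 0.13. With fry, bipolar cells, astrocytes and growth factors passed, and with probes above background at 0.01 on all 12 arrays hypoxia and synapse genes no longer did. Pericyte genes passed without a filter and with array weights, and resting Müller glia genes did not with array weights. In at least 1 setting the median of 17 of the 19 called lists moved by over 1.5 times. Without a filter the medians were 0.45 for complement, 0.26 for interferon-stimulated genes and 0.34 for MHC class II. In the values as deposited they were 0.67 for interferon-stimulated genes and -0.10 for amacrine and horizontal cells. After normexp with an offset of 16 the MHC class I median was 0.67. These lists kept their calls in those settings. The number of probes higher was 1111 in the values as deposited, against 436. The number lower was 929 after median scaling and 248 without IR 3 and Control 5 together, against 382, and 203 to 379 when 1 array was left out. Probes higher by at least 2-fold numbered 64 with an offset of 50, 160 in the values as deposited and 170 after normexp with an offset of 16, against 97. Probes lower by at least 2-fold numbered 18 after median scaling and 22 after normexp with an offset of 16, against 6, and 3 to 11 when 1 array was left out. A larger offset shrinks differences of dim probes by construction, and leaving out arrays lowers the number of samples. For the other shifts, of counts and of lists, the cause was not tested. The values as deposited kept a background that differed between the groups. The mode of the intensities was 41.6 to 52.0 on IR arrays and 38.5 to 46.0 on Control arrays. Median intensity was 59.0 to 69.8 on IR arrays and 52.1 to 63.9 on Control arrays. Whether this accounts for the shifts in that setting was not tested. Of the 818 calls, 659 were shared in the values as deposited, 714 after median scaling, 714 after cyclic loess and 492 without IR 3 and Control 5. Of the 94 called genes named here, 71 kept their call in all 24 settings where they were tested, 23 lost it in at least 1 setting, 16 of them in a fit that left out 1 array, and none changed direction; of 13 not called, 5 passed in some setting. Not run were the background correction from detection p-values, since the signal columns carry names that match no sample label, and the chip as a block, since the headers name 1 chip. The setting without background correction was the one reported, and the filters on detection p-values were run with the background estimate in their place. Signal over background limits dim probes, since values near the mode of an array carry little of the transcript's change.

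The replicate numbers 1 to 6 occur in both groups. Arrays with the same number deviated together in some pairs and not in others (r across probes of -0.03, 0.48, 0.38, 0.23, -0.01 and 0.18). Control and IR arrays were each other's best partner for the numbers 2, 3 and 4. The best partner of IR 6 was Control 6, though not the reverse, and neither held for the numbers 1 and 5. A pairing of some arrays is therefore not excluded, and the main fit does not take it into account. With the replicate block 434 probes were higher and 775 were called in all, 606 of them shared with the unblocked calls. Of the named genes 6 lost a call (Vwf, Cxcl1, Slc7a11, Id3, Slco1c1 and Th) and 2 gained one (Lcn2 and Sncg), no main list changed its call, and retinal pigment epithelium genes passed (median -0.21, adjusted p = 0.033, up to 0.47 over all settings).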

Other observations

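In this part the lists were drawn up after the values were seen, leaving out the members whose values had prompted them, and the tests were written down before the values of the remaining members were seen. Set only after these were seen were the removal of Nfkbia, a gene already examined, from the glucocorticoid list, the wording of the clock explanation, with its bounds kept, and the requirement that a list hold under all 4 scalings, without which the lysosome and ribosomal lists would have met their predictions. Differences are mean list scores, IR minus Control, tested by exact permutation over 924 splits of the arrays and adjusted over 5 lists. None of the measured members belongs to a list described in the report.

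Genes of sterol synthesis were lower in injured retinas. Insig1, a regulator of the pathway, was at -0.82 ± 0.14 (SE, limma adjusted p = 0.0051), and of 11 further genes 6 were called lower, none higher and 10 lay below 0. Idi1, an enzyme that makes the isoprenoid building block, was at -0.61, Fdft1, squalene synthase, at -0.46, and Msmo1, Nsdhl, Sqle and Fdps were at -0.43, -0.38, -0.36 and -0.36. The mean score differed by -0.29 ± 0.04 (SE, exact permutation p = 0.0022, the smallest possible here, adjusted p = 0.011), and camera with an estimated correlation gave an adjusted p of 0.020. The difference was -0.41 after median scaling, -0.26 after cyclic loess and -0.26 in the values as deposited, each with an exact permutation p of 0.011 or less. A lower level of sterol synthesis transcripts is a hypothesis from these data and may reflect either less transcript per cell or a different mix of cells, which was not tested.

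Genes induced by glucocorticoids were examined because Per1 (-0.79, adjusted p = 0.026) and Dusp1 (-0.63, adjusted p = 0.024) were lower. Of 6 further genes Sgk1 was called at -0.59, and 5 of the 6 lay below 0, among them Tsc22d3 at -0.26 and Klf9 at -0.23. The mean score differed by -0.22 ± 0.06 (SE, exact permutation p = 0.0065, adjusted p = 0.011) and stayed below 0 in each scaling (-0.34 to -0.18). Less glucocorticoid action in IR stays a hypothesis, found on these data and resting on 1 called gene. Camera, which compares the list with other genes, did not pass (adjusted p = 0.057, and 0.16 with an estimated correlation). Clock output genes, to which Per1 belongs, gave no such difference. Over 7 genes the mean score differed by -0.002 ± 0.07 (SE, test value -0.00206, exact permutation p = 0.97), which argues against a mean decrease of 0.2 or more. Its sign turned with the scaling (-0.07 after median scaling, 0.10 in the values as deposited), and Per2 was at -0.30 and Bhlhe40 at 0.30.

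Lysosome genes were examined because Ctsc (1.42, adjusted p = 7.3e-04) and Smpdl3a (1.55, adjusted p = 0.057) had large differences. Of 17 further genes 4 rose, Lamp2 by 1.03, Cd63 by 0.86, Ctsl by 0.82 and Grn by 0.58, and the mean score differed by 0.21 ± 0.05 (SE, exact permutation p = 0.0043, adjusted p = 0.011). Camera gave an adjusted p of 0.0074, and of 0.15 with an estimated correlation. After median scaling it was 0.09 (exact permutation p = 0.24), so a rise of the whole list cannot be told apart from a shift by scaling. The same holds for 49 ribosomal protein genes, of which 3 rose, Rps2 by 1.11, Rplp1 by 0.73 and Rps12 by 0.64. Their mean score differed by 0.28 ± 0.10 (SE, exact permutation p = 0.030, adjusted p = 0.038), but by 0.12 after median scaling (exact permutation p = 0.41). Camera with an estimated correlation gave an adjusted p of 0.15, and the exact permutation p was 0.061 without IR 3.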
